A study of Mus musculus with 16 samples.

How the data were processed

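RNA was sequenced from regulatory T cells (Treg, the Foxp3-expressing CD4 T cells that restrain other immune cells) and conventional T cells (Tconv) sorted from visceral adipose tissue (VAT) of mice. The mice either lacked Hpgd in their Treg or were wild type (WT) controls, and are called KO and WT here. Hpgd encodes hydroxyprostaglandin dehydrogenase, the enzyme that inactivates prostaglandin E2. Per the labels, the mice were 12 weeks old and of the C57BL/6JRcc strain. Per the labels' protocols, animals were perfused with saline, the fat was digested with collagenase and DNase, and cells were sorted by flow cytometry. The markers used for sorting are not given in the sources used here. Libraries were prepared from 10 ng of RNA with SMART-seq2, a full-length protocol that does not mark the strand, and sequenced on an Illumina NextSeq, with base calls converted by bcl2fastq2 2.20, per the same protocols. Sample titles gave the 4 groups: 3 Treg WT, 4 Treg KO, 4 Tconv WT and 5 Tconv KO libraries. The label for the mouse line was identical in all 16 samples, so genotype rests on the titles. The series description gives 5 deleted and 4 WT animals, but the labels do not tie libraries to animals. The p-values therefore measure the spread between these libraries.

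The deposited table holds a never-negative signal for 19540 genes in 16 libraries, which are gene read counts divided by a size factor of the library, plus 1, as its values show. A gene with no reads is listed at 1. The submitters' processing notes name CASAVA 1.8, kallisto 0.44, Partek 6.6, R 3.3.1, DESeq2 with no version, and the mouse build mm10, without roles or order. The annotation used for counting and whether counting used strand are not given in the sources used here. The steps between low values gave the worth of 1 read in each library, and 100% of the values under 1000 reads came out whole within 0.1 of a read, at a largest distance of 0.00480. Read totals per library came from these steps. If the input was estimated counts, they had been rounded. The floor, the value of 3 reads in a library, ran from 1.38 in the deepest library to 7.09 in the shallowest. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

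Values were transformed to log2 of the deposited value plus 1, so fold changes are on that scale and understate the change of low genes. Genes at 10 or more in at least 3 libraries were tested, which kept 14319. A single limma 3.58.1 model in R 4.3.3, with a mean-variance trend and all 16 libraries, gave 2-sided p-values for 5 comparisons: Treg KO against Treg WT, Tconv KO against Tconv WT, the difference between these effects, and Treg against Tconv within WT and within KO. The 4 groups shared 1 estimate of the spread because they are small. Adjusted p is from limma with Benjamini-Hochberg adjustment per comparison throughout, and a gene passed at an adjusted p under 0.05. Hpgd, which did not reach the filter, was compared by an exact 2-sided permutation test.

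The 26 gene lists were fixed before the data were examined, as were the comparisons, tests, filter and all alternatives except those named below. The lists held Treg core genes, VAT Treg genes, prostaglandin genes, PPAR and lipid genes, Th1 and cytotoxic, Th2, Th17, naive, activation, immediate early, cAMP response, proliferation, interferon, NF-kB, oxidative phosphorylation, glycolysis and ribosomal protein genes. Markers of macrophages, dendritic cells, B cells, CD8 T and NK cells, type 2 innate lymphoid cells, neutrophils and mast cells, adipocytes, stromal cells, and red cells and platelets made up the rest. Some lists share members, so their calls are not independent of each other. Each list was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists. Camera with an estimated correlation, and fry, stood beside it. Genes were named by a rule: Hpgd and Foxp3; among genes that passed, whose groups did not overlap and whose higher mean was at least 50, the 8 highest and 8 lowest fold changes (5 and 5 for the difference, without the overlap condition); where none passed, the 3 smallest p-values in each direction; up to 4 members with the smallest p of each list described; and up to 3 members with the highest mean of each marker list. Genes with only an identifier and antigen receptor segments were not named among the extremes. A few genes that the rule picked are not reported here; they still count in totals of genes and lists.

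Positions are from GENCODE M21, on the same build as mm10, in which 19232 symbols (98.4%) were found. Of 125 genes picked by the rule or shown, 35 had an exon that overlaps an exon of another annotated gene, in 13 cases a protein coding one. Their reads cannot be told apart without strand, so such genes are uncertain, as are members of the haemoglobin, Klr, Ly6, H2, granzyme and serpin families. The overlap check was added after the results were seen.

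Alternatives were quantile scaling, centring on the median, pseudocounts of 0.1 and 8, no filter and a filter at 50, a robust prior, sample quality weights, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. For the comparisons that use both cell types, the block was the genotype together with the number, as if it marked an animal. Added after seeing the data were a pseudocount of 0, voom weights on the recovered reads, leaving out Tconv WT 1, Tconv WT 3 and Tconv KO 3 together, and thinning Tconv KO 3 to the median depth of the others. The steps were tested on simulated data with known changes. These were planted only in genes with a mean of at least 50, so the shares recovered do not hold for lower genes that were tested. For Treg KO against Treg WT, 17.9%, 68.7% and 83.3% of genes changed 2-fold, 4-fold and 8-fold were recovered over 13663 genes, and 12 unchanged genes were called beside 12, 46 and 55 recovered ones, a share above the 5% aimed for. For Tconv KO against Tconv WT the shares were 25.4%, 70.1% and 92.4% over 13647 genes, and for the difference 5.97%, 34.3% and 65.2% over 13635. They were 22.4%, 67.2% and 86.4% over 13745 genes for Treg against Tconv in WT, and 23.9%, 82.1% and 92.4% over 13734 in KO. All libraries were kept. The least different pair within a group differed at a chi-square per degree of freedom of 27.1. That measure sets reads against counting error alone, so it cannot show that libraries come from different animals.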

Results

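The series profiled gene expression in Treg and Tconv from the visceral fat of WT mice and of mice whose Treg lacked Hpgd. It asked what loss of this prostaglandin-inactivating enzyme does to VAT Treg and to the Tconv beside them. There were 3 Treg WT, 4 Treg KO, 4 Tconv WT and 5 Tconv KO libraries. Treg WT libraries held 9.10, 8.20 and 7.57 M reads, and Treg KO libraries 6.97, 4.77, 5.84 and 8.74 M. Tconv WT libraries held 7.17, 3.39, 7.88 and 6.42 M reads. Of the Tconv KO libraries, 4 held 5.90, 9.26, 8.95 and 7.74 M, while Tconv KO 3 held 56.7 M. Between 13366 and 16041 genes had reads in a library, and log2 values of libraries in the same group correlated across genes at r from 0.828 to 0.917. The first principal component carried 19.7% of the variance and separated all Treg from all Tconv libraries, and the second carried 9.31%. Levels below are means ± SD of the normalised values, over n = 3 (Treg WT), 4 (Treg KO), 4 (Tconv WT) and 5 (Tconv KO) libraries.

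Hpgd lies on chromosome 8 at 56294585 to 56321043 on the plus strand (mm10), with 7 annotated exons. It read 73.1 in Treg WT 1 and 56.0 in Treg WT 2, but 4.31 (3 reads) in the library labelled Treg WT 3. The Treg KO libraries read 3.41, 2.54, 2.42 and 1.00, from 2, 1, 1 and 0 reads. Mean levels were 44.5 ± 35.8 in Treg WT and 2.34 ± 0.998 in Treg KO, a log2 difference of −3.13. The exact permutation test gave p = 0.0571, the smallest that the 35 splits of 7 libraries allow, so this test cannot pass 0.05 with these group sizes. In limma the unadjusted p of Hpgd was 0.000699, and 0.546 adjusted over all 19536 genes with reads. Each Treg WT library read above every Treg KO library, but the library labelled Treg WT 3 did so only at 3 reads against at most 2, so the size of the difference rests on Treg WT 1 and 2. The labels do not say which exon was deleted, and gene-level values hold all exons. Of the 9 Tconv libraries, Hpgd had reads only in Tconv KO 3, the deepest, at 6.20 from 41 reads. That level lies above each Treg KO library and the library labelled Treg WT 3. Foxp3, the transcription factor that defines Treg, stood at 407 ± 182 in Treg WT and 403 ± 120 in Treg KO. It stood at 15.5 ± 18.4 in Tconv WT and 1.98 ± 1.73 in Tconv KO. Since cells were sorted on markers the labels do not give, Foxp3 is reported as a check of the sort, and its exons overlap those of Ccdc22 and Ppp1r3f.

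**Figure D1:**
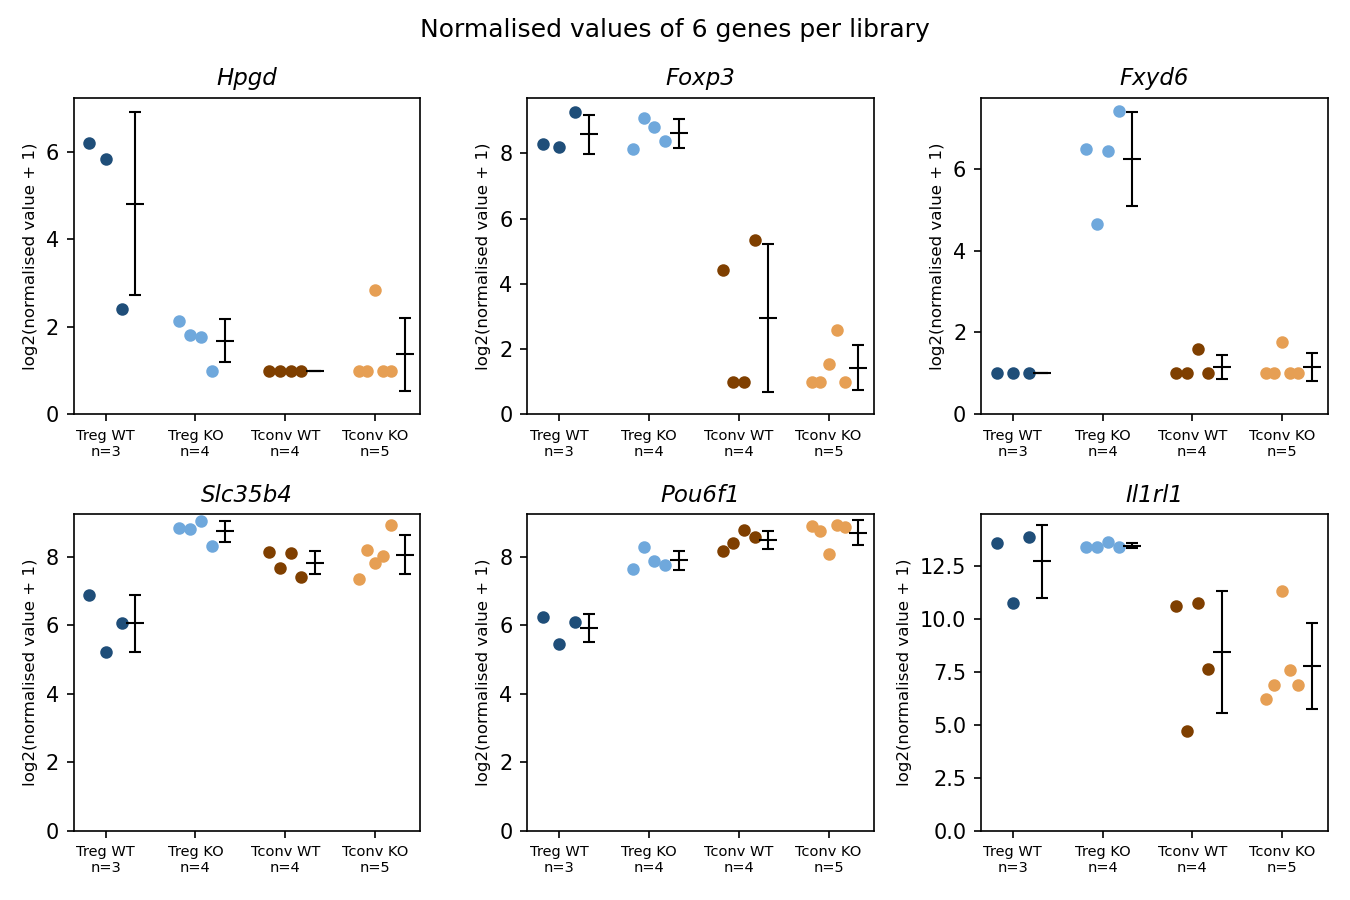
Each point is 1 library (n = 3 Treg WT, 4 Treg KO, 4 Tconv WT, 5 Tconv KO) for Hpgd, Foxp3, Fxyd6, Slc35b4, Pou6f1 and Il1rl1, the y axis is log2 of the normalised value plus 1, and bars are means ± SD of these log2 values. Hpgd in the library labelled Treg WT 3 (4.31 on the linear scale) lies beside the Treg KO libraries, and Fxyd6 has no reads in the 3 Treg WT libraries and has reads in the 4 Treg KO libraries.

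In Treg, 3 genes rose with Hpgd deletion and 0 fell, of 14319 tested. The Treg WT libraries had reads for 14216, 14874 and 14283 genes, and the Treg KO libraries for 15193, 16041, 15135 and 15856. Each Treg KO library thus had reads for more genes than each Treg WT library. Whether this shift bears on the one-way calls, or on genes unread in WT, was not tested, though 3 genes also passed under quantile scaling. Fxyd6, a regulator of ion transport (chromosome 9, 45370185 to 45396159), had no reads in Treg WT and 91.3 ± 58.7 in Treg KO. That is at least 23.5-fold higher against a floor of 3 reads per library (log2 change 5.24, SE 0.72, adjusted p = 0.00849). Slc35b4, a nucleotide sugar transporter (chromosome 6, 34153380 to 34177111), rose from 73.3 ± 41.4 to 435 ± 86.9 (2.69, SE 0.42, adjusted p = 0.0247). Pou6f1, a POU-domain transcription factor (chromosome 15, 100575318 to 100599984), rose from 61.4 ± 16.4 to 240 ± 48.0 (1.97, SE 0.33, adjusted p = 0.0389). In Tconv, whose Hpgd was not targeted, Slc35b4 read 232 ± 54.1 in WT and 284 ± 121 in KO, and Pou6f1 359 ± 65.1 and 425 ± 89.9. Exons of Slc35b4 overlap an antisense transcript, Gm13856, so its level is uncertain without strand. All 3 calls were lost without the library labelled Treg WT 3, at adjusted p = 0.0984 for Fxyd6 and 0.118 for the other two. Slc35b4 was also lost without Treg WT 2, Treg KO 1, Treg KO 2 or Treg KO 3 (0.142, 0.0909, 0.125 and 0.111), and Pou6f1 without those or Treg KO 4 (0.194, 0.0909, 0.152, 0.111 and 0.124). The count was 17 without Treg WT 1, 0 without the library labelled Treg WT 3, 1 without Treg KO 1 and 1 without Treg KO 2; it was 1 with a filter at 50 or with quality weights, and 0 with only these groups in the fit and by voom, where 650 genes had an unadjusted p under 0.05. With the replicate number as a block the count was 0, at adjusted p = 0.0536 for Fxyd6 and Slc35b4 and 0.335 for Pou6f1. With a filter at 50 Fxyd6 was lost (0.385) and Slc35b4 kept. Pou6f1 was lost with that filter (0.0575) and with none (0.0525), and it and Slc35b4 with quality weights (0.0726). In the main limma fit 890 genes had an unadjusted p under 0.05, against 716 expected by chance, and 860 genes (6.01%) had groups that did not overlap, against 5.71% by chance. In a check added after seeing the data, 3 of 35 splits of these libraries, the real one included, gave as many genes. Chance can therefore not be excluded for the 3 calls.

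No Treg-defining programme passed the test in this comparison: 0 of the 26 lists were called. That count was not stable, at 1 under quantile scaling, with the replicate number as a block or without Treg KO 4. It was 2 without Treg KO 3, and 3 without Treg KO 2 or without the library labelled Treg WT 3. Of the Treg core genes 0 of 25 passed (camera adjusted p = 0.926), with Tnfrsf4, the costimulatory receptor OX40, at 11937 ± 2867 in WT and 17423 ± 3386 in KO, and Entpd1, an ectonucleotidase, at 923 ± 542 and 398 ± 167. Of the VAT Treg genes 0 of 23 passed (0.677), with Cish, a suppressor of cytokine signalling, at 3588 ± 973 and 5642 ± 1053 and Tnfrsf1b, a TNF receptor, at 2879 ± 641 and 4041 ± 811. Prostaglandin genes gave 0 of 19 (0.513), with the prostaglandin E2 receptor Ptger4 at 500 ± 58.5 and 761 ± 114 and the thromboxane receptor Tbxa2r at 30.8 ± 45.4 and 73.0 ± 72.6. Among PPAR and lipid genes, 0 of 33 passed (0.709), with the fatty acid transporter Cd36 unread in WT and at 17.8 ± 12.2 in KO, and the desaturase Scd2 at 4.04 ± 5.27 and 31.0 ± 11.4. Th1 and cytotoxic genes gave 0 of 23 (0.926), with the chemokine Ccl3 at 35.3 ± 42.0 and 108 ± 101, and their mean changed sign under quantile scaling. cAMP response genes gave 0 of 20 (0.513), with the phosphodiesterase Pde7a at 64.8 ± 48.3 and 111 ± 17.4. Naive T cell genes had the smallest list p (0.0771), with 14 of 17 members positive. Adjusted over the list alone, 3 of these 17 passed, each at 0.0423, among them the kinase Txk (38.3 ± 36.6 and 108 ± 61.4) and the trafficking factor Klf2 (1651 ± 848 and 2680 ± 359), which was named after its values were seen. Over all genes none of the 17 passed, and no member of another list passed when adjusted over the list alone. Before rescaling, the mean log2 change of every list was positive in this comparison, not only that of the naive genes.

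In Tconv, where Hpgd was not targeted, 0 genes passed between KO and WT in limma; the smallest adjusted p was 0.656. The 3 genes with the smallest p in each direction are given, though none passed. Pf4, a platelet chemokine, read 27.2 ± 5.39 in WT and had no reads in KO, at least 8.29-fold lower. Nphp4, a cilium protein, read 54.7 ± 55.6 and 1.32 ± 0.714, and Gemin8, part of the complex that assembles spliceosomal particles, 216 ± 103 and 41.2 ± 30.3. In the other direction, Nicn1 read 1.51 ± 1.01 in WT and 55.8 ± 33.3 in KO, the mitochondrial protease Oma1 12.0 ± 12.4 and 104 ± 26.1, and Rcbtb1 113 ± 58.1 and 332 ± 48.4. At an unadjusted p under 0.05 there were 781 genes, against 716 by chance, and 239 (1.67%) had groups that did not overlap, against 1.59% by chance. The voom fit called 0, with 1311 genes under 0.05 unadjusted.

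Of the lists, red cell and platelet genes were lower in Tconv KO (camera adjusted p = 1.08e-07, 0 of 7 members called), a call lost at adjusted p = 0.149 with an estimated correlation. Adjusted over the list alone, 4 of the 7 were lower: Pf4, the alpha globins Hba-a1 and Hba-a2 and the beta globin Hbb-bt. Hba-a2 read 112366 in Tconv WT 3 alone, with group levels of 28347 ± 56014 in WT and 76.4 ± 54.4 in KO, and reads may be split between the near-identical globin copies. The call was lost, at an adjusted p of 0.476, when Tconv WT 1, Tconv WT 3 and Tconv KO 3 were left out, a choice made after seeing the data. Tconv WT 1 carried neutrophil transcripts, with S100a8 at 10195 and S100a9 at 4204, and the neutrophil list reached 0.0929, as did Treg core genes; ribosomal protein genes reached 0.0630. None of the members of the lists for prostaglandin, VAT Treg, lipid, Th1, naive and cAMP genes passed over all genes or over the list alone. Ptgr1, a prostaglandin reductase, read 2.10 ± 1.59 in WT and 27.2 ± 33.6 in KO, and Tbxa2r 77.6 ± 54.1 and 210 ± 89.8. The Treg core members with the smallest p were Ebi3, a cytokine subunit (2.01 ± 2.03 and 38.6 ± 42.3), and Socs2 (1103 ± 386 and 652 ± 236). Granzyme B, Gzmb, read 113 ± 120 and 339 ± 100, the chemokine receptor Cxcr6 3780 ± 806 and 2203 ± 939, and the IL-7 receptor Il7r 5482 ± 672 and 4272 ± 577. The lipid droplet protein Plin3 read 526 ± 182 and 197 ± 63.1.

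Whether the effect of the deletion differed between Treg and Tconv was tested as a difference of the 2 effects, and 0 genes passed in limma (748 at an unadjusted p under 0.05, against 716 by chance; voom 0, with 846). Fxyd6 had the smallest p, with a difference of 5.23 (adjusted p = 0.293), as it stood at 1.25 ± 0.503 in Tconv WT and 1.28 ± 0.623 in Tconv KO. Rimkla, a ligase of N-acetylaspartate and glutamate whose exons overlap Zmynd12, read 137 ± 59.8 in Treg WT, 7.53 ± 13.1 in Treg KO, 1.75 ± 1.51 in Tconv WT and 31.4 ± 32.2 in Tconv KO (−7.97, adjusted p = 0.293). Both passed without Treg KO 2 (adjusted p = 0.0350), and Rimkla without Tconv KO 3 (0.0377). Tacc3, a spindle protein overlapping Tmem129, had no reads in Treg WT and 61.2 ± 20.2 in Treg KO, with 92.0 ± 39.2 and 82.2 ± 74.4 in Tconv WT and KO. Nphp4 gave 6.16 (adjusted p = 0.552), Invs, overlapping Tex10, −2.78 (0.620) and Atxn7l1os2, overlapping Atxn7l1, −5.18 (0.928). Effects of the deletion in Treg and in Tconv correlated across genes at r = 0.035, where genes are not independent replicates. Foxp3 gave 1.55 (adjusted p = 0.959).

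Ribosomal protein genes differed upward between the effects (37 of 40 members positive, 0 called, camera adjusted p = 0.00258), and so did red cell and platelet genes (6 of 7 positive, 0 called, 0.000695). Both were lost at adjusted p = 0.638 with an estimated correlation. Adjusted over the list alone, 1 of these members passed, Pf4. The ribosomal call was also lost under quantile scaling (0.227) and without Treg WT 2 (0.0957), Tconv WT 3 (0.223), Treg KO 1 (0.188), Treg KO 4 (0.108) or Tconv KO 2 (0.194). Without Tconv WT 1, Tconv WT 3 and Tconv KO 3 together, the ribosomal list gave 0.277 and the red cell list 0.431.

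Between Treg and Tconv of WT mice, 599 of 14319 genes passed, 315 higher and 284 lower in Treg, and 547 changed at least 2-fold. Cyp4f18, a leukotriene-metabolising cytochrome P450, stood highest at 5436 ± 2231 in Treg and 1.52 ± 1.03 in Tconv (log2 difference 11.05, SE 0.78, adjusted p = 8.94e-08), with exons that overlap Zfp961. Next came Slco2b1, an organic anion transporter, at 1046 ± 641 and 3.54 ± 5.07 (8.09, SE 0.78, adjusted p = 3.92e-06), and Wipf3, whose exons overlap Scrn1, at 862 ± 647 and 3.03 ± 4.06. Frmd5 (1085 ± 187 and 16.1 ± 24.3), Ky (342 ± 137 and 2.52 ± 3.05), the chemokine receptor Ccr1 (874 ± 770 and 11.9 ± 19.8), the steroid-synthesis enzyme Cyp11a1 (841 ± 602 and 9.32 ± 5.15) and the protease Ctsh (813 ± 222 and 12.5 ± 11.8) followed. Lowest in Treg was Klrk1, the activating receptor NKG2D, at 1.61 ± 1.05 against 562 ± 375 (−7.64). The chemokine Xcl1 and the follicular homing receptor Cxcr5, whose exons overlap Bcl9l, had no reads in Treg WT, at least 125-fold and 99.9-fold lower than in Tconv (487 ± 417 and 389 ± 276). Tconv WT 4 alone, at 1106, raised the mean and the bound of Xcl1, as the other 3 read 205 to 343. Themis, a T cell receptor signalling protein, read 9.10 ± 3.61 against 1323 ± 232, and granzyme K, Gzmk, 23.9 ± 19.9 against 1704 ± 229. Serpina3f (17.5 ± 28.7 and 700 ± 260), the transcription factor Eomes (16.4 ± 26.7 and 646 ± 248) and Esm1 (5.26 ± 7.38 and 398 ± 140), which lies within the span of Gzmk on the other strand, were the remaining ones. Of the 599 genes, 561 had groups that did not overlap; over all genes 12.0% did, against 5.71% by chance. The count fell to 339 without the library labelled Treg WT 3, to 310 with only these groups in the fit (297 shared) and to 288 by voom (284 shared), and voom lost Wipf3, Frmd5, Ccr1, Eomes and Esm1 at adjusted p from 0.0556 to 0.158.

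Treg core genes were higher in WT Treg: 12 of 25 passed and 0 were lower (14 and 1 adjusted over the list alone; camera adjusted p = 5.67e-15). Since the cells were sorted as Treg and Tconv, this list, like Foxp3 alone, is a check of the sort in both genotypes. Foxp3 was higher by 5.64 (SE 0.95, adjusted p = 0.00144), the costimulatory receptor Tnfrsf18 (GITR) read 10000.3 ± 1132 against 2918 ± 123 in Tconv, and the Treg transcription factor Ikzf2 3745 ± 1178 against 581 ± 243. The anti-inflammatory cytokine Il10 read 13572 ± 9195 against 429 ± 317 (4.86, adjusted p = 3.99e-05), and Tnfrsf4 11937 ± 2867 against 3289 ± 1300. VAT Treg genes gave 11 higher and 0 lower of 23 (15 and 1 adjusted over the list alone; 1.92e-13), led by Ccr3 at 1741 ± 624 against 44.1 ± 36.5, Klrg1, a receptor of terminally differentiated lymphocytes, at 12560 ± 5645 against 549 ± 391, and Gata3, a type 2 transcription factor, at 12394 ± 4314 against 3126 ± 999. The IL-33 receptor Il1rl1, also on this list, read 9716 ± 7020 against 885 ± 897 (4.30, adjusted p = 0.0490). Its call was lost without Treg WT 1 (0.146), the library labelled Treg WT 3 (0.192), Tconv WT 2 (0.137) or Tconv WT 4 (0.113), by voom (0.145) and under quantile scaling (0.0562). It was also lost with only these groups in the fit (0.126), a robust prior (0.110), no filter (0.0675), and pseudocounts of 0.1 (0.0554) and 0 (0.0564). In Tconv, Il1rl1 was uneven, at 1566 in Tconv WT 1, 1746 in Tconv WT 3 and 2548 in Tconv KO 3, libraries that also read Pparg at 316, 485 and 398.

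Th1 and cytotoxic genes were lower in WT Treg, with 14 of 23 lower and 0 higher (18 and 0 adjusted over the list alone; 2.03e-19). The monocyte and T cell surface gene Ly6c2 read 62.4 ± 40.8 against 2144 ± 1333, and the death ligand Fasl 38.9 ± 4.99 against 1690.5 ± 253. Naive T cell genes gave 8 lower and 0 higher of 17 (11 and 0 adjusted over the list alone; 6.17e-12). Tcf7, a transcription factor of resting and memory T cells, read 252 ± 135 against 3768 ± 663 (−4.01, SE 0.43, adjusted p = 1.13e-05), Txk 38.3 ± 36.6 against 371 ± 53.3, and Igfbp4 14.4 ± 3.05 against 206 ± 98.3, the last pair lost by voom (0.0808 and 0.104). CD8 T and NK cell markers gave 4 lower of 11 (6 adjusted over the list alone; 1.20e-06), among them Klrd1, without reads in Treg and at 93.5 ± 33.9 in Tconv, at least 24.1-fold lower. With an estimated correlation these 5 lists held, at adjusted p = 0.000499 (Treg core), 0.0062 (VAT Treg), 0.000952 (Th1), 0.000629 (naive) and 0.00858 (CD8 T and NK).

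Members of the NF-kB list went both ways in WT, with 7 higher and 2 lower of 19 (11 and 3 adjusted over the list alone; 4.65e-05, and adjusted p = 0.307 with an estimated correlation). The adhesion molecule Icam1 read 3519 ± 550 in Treg against 1566 ± 332, the NF-kB subunit Nfkb1 8039 ± 3186 against 2690 ± 1110, and the cytokine Tnf 427 ± 143 against 1084 ± 77.2. Interferon-stimulated genes gave 3 lower of 28 (4 adjusted over the list alone; 0.0016, and adjusted p = 0.251 with an estimated correlation), of which the GTPase Irgm1 read 327 ± 105 against 812 ± 133. Oas3, another of them, was lost without Treg WT 2, the library labelled Treg WT 3 or any 1 of the 4 Tconv WT libraries (adjusted p from 0.0501 to 0.149). It was also lost without Tconv WT 1, Tconv WT 3 and Tconv KO 3 together (0.0965), with only these groups in the fit (0.0915), with quality weights (0.0945) and by voom (0.112). Activation genes gave 5 higher and 2 lower of 20 (8 and 4 adjusted over the list alone; 0.0437, and adjusted p = 0.257 with an estimated correlation). The inhibitory receptor Ctla4 read 7160 ± 1382 against 2668 ± 343 and Cd200 19.3 ± 18.7 against 295 ± 226, the latter lost by voom (0.0745) and with only these groups in the fit (0.0659). That list was lost without Treg WT 1 (0.0579), the library labelled Treg WT 3 (0.356), Tconv WT 2 (0.0707) or Tconv WT 4 (0.0737), and under quantile scaling (0.146). Of the activation genes, Ctla4, Tnfrsf4, Tnfrsf9, Icos and Tigit are also Treg core genes. PPAR and lipid genes were not called (0.0658), with 4 higher and 1 lower of 33 over all genes and over the list alone; the lipid droplet protein Plin2 read 8430 ± 3261 against 1247 ± 961, and the stearoyl desaturase Scd2 4.04 ± 5.27 against 148 ± 19.96, a call lost without the library labelled Treg WT 3 (0.0640) and by voom (0.576). Th2 genes were not called either (0.160), with 2 higher and 1 lower of 10 (3 and 1 adjusted over the list alone). Of prostaglandin genes (0.416), 1 of 19 passed (2 adjusted over the list alone): Ptger4 was lower in Treg, at 500 ± 58.5 against 1104 ± 148 (−1.14, adjusted p = 0.00411), with exons overlapping Ttc33. Hpgd itself stood at least 9.08-fold higher in WT Treg than in WT Tconv, where it had no reads, and that ratio rests on Treg WT 1 and 2.

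**Figure D2:**
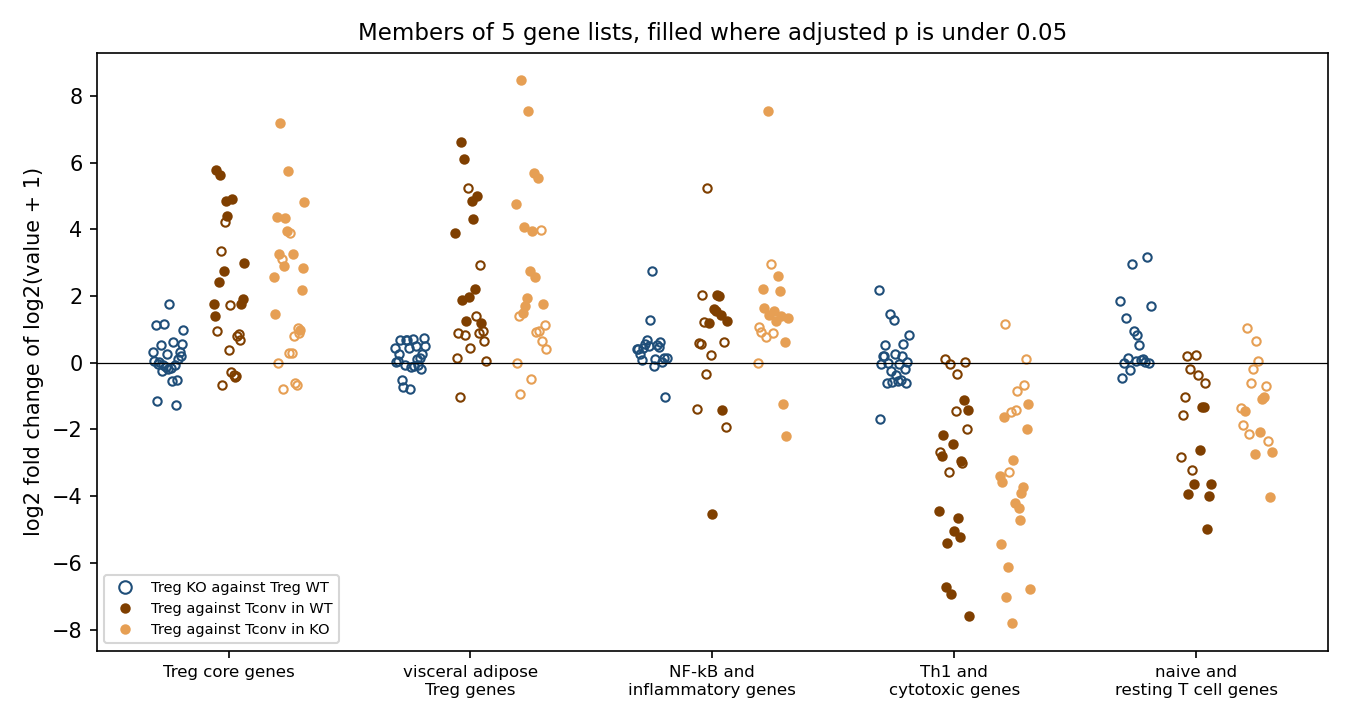
Each point is 1 tested gene of 5 lists (Treg core, VAT Treg, NF-kB, Th1 and cytotoxic, naive), placed by its log2 fold change in Treg KO against Treg WT, in Treg against Tconv of WT, and in Treg against Tconv of KO, and filled where the limma adjusted p was under 0.05. No member is filled in Treg KO against Treg WT, while 12 and 14 of the 25 Treg core genes are filled, all higher in Treg, in the WT and KO comparisons of Treg with Tconv.

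In KO mice, 975 of 14319 genes passed between Treg and Tconv, 595 higher and 380 lower in Treg, and 788 changed at least 2-fold. Cyp4f18 again stood highest, at 8533 ± 5036 against 7.71 ± 9.30 (10.32, SE 0.69, adjusted p = 1.98e-08). Slco2b1 had no reads in Tconv KO and 1613 ± 650 in Treg KO, at least 491-fold higher (adjusted p = 6.06e-08), and Ky 361 ± 59.6, at least 110-fold higher. Ccr1 read 945 ± 472 against 1.49 ± 0.734, the neutrophil-attracting chemokine Cxcl2 4545 ± 1152 against 127 ± 237, and Jcad, an endothelial junction protein, 376 ± 65.2 against 1.20 ± 0.387. Tconv KO 3 carried most of that Cxcl2 level, at 548 where the other Tconv KO libraries reached 68.8. The antigen presentation gene H2-Eb1 read 1536 ± 719 against 21.8 ± 34.9, and Foxp3 was higher by 7.19 (adjusted p = 1.64e-05). Gzmk was lowest, at 27.1 ± 35.7 in Treg against 2955 ± 1459 (−7.82, SE 0.89, adjusted p = 1.30e-05), followed by Esm1 (32.5 ± 59.9 and 1171 ± 634), Eomes (14.4 ± 16.02 and 1308 ± 807) and Xcl1 (3.79 ± 4.62 and 406 ± 128). Slc26a11, a sulfate transporter (3.68 ± 5.35 and 285 ± 76.0), Cpne7 (14.1 ± 22.7 and 562 ± 150), Samd3 (2.70 ± 3.41 and 249 ± 106) and Cxcr5 (6.76 ± 11.5 and 309 ± 148) followed. Of the 975 genes, 845 had groups that did not overlap; over all genes 10.7% did, against 1.59% by chance.

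Treg core genes gave 14 higher and 0 lower of 25 in KO (19 and 1 adjusted over the list alone; camera adjusted p = 1.92e-17), with Tnfrsf18 at 11418 ± 1232 against 2541 ± 442, Tnfrsf4 at 17423 ± 3386 against 2399 ± 348, Ikzf2 at 3478 ± 575 against 462 ± 62.4 and the actin-capping protein Capg at 8012 ± 1414 against 1412 ± 609. VAT Treg genes gave 13 higher and 0 lower of 23 (17 and 1 adjusted over the list alone; 7.44e-16). Gata3 read 16254 ± 3613 against 2583 ± 1444, Il10 10917 ± 5945 against 619 ± 109, Klrg1 12793 ± 3445 against 383 ± 326, and Il1rl1 11290 ± 945 against 609 ± 1085 (5.69, adjusted p = 0.00168). PPAR and lipid genes gave 6 higher and 0 lower of 33 over all genes and over the list alone (0.00177). The triglyceride synthase Dgat2 read 1241 ± 422 against 19.7 ± 16.3 (6.51, SE 0.71, adjusted p = 7.97e-06), Plin2 7334 ± 2561 against 753 ± 626, and the lipid droplet protein Hilpda 7210 ± 2436 against 1898.5 ± 1895, with 1835 and 5219 for the last pair in Tconv KO 3. Th1 and cytotoxic genes gave 16 lower and 0 higher of 23 (20 and 1 adjusted over the list alone; 4.16e-21), with Fasl at 50.5 ± 46.5 against 1868 ± 549. Naive genes gave 7 lower and 0 higher of 17 (11 and 1 adjusted over the list alone; 6.03e-08), with Tcf7 at 283 ± 220 against 3759 ± 626 and Ccr7, a lymph node homing receptor, at 486 ± 173 against 1290 ± 107. CD8 T and NK markers gave 4 lower of 11 (6 adjusted over the list alone; 2.69e-05), with Klrd1 at least 8.91-fold lower, as it had no reads in Treg KO and read 43.2 ± 15.03 in Tconv KO. These 6 held with an estimated correlation, at 0.00023 (Treg core), 0.00315 (VAT Treg), 0.0494 (PPAR), 0.000976 (Th1), 0.00304 (naive) and 0.0228 (CD8 T and NK).

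NF-kB genes gave 11 higher and 2 lower of 19 in KO (14 and 2 adjusted over the list alone; 9.82e-09, and adjusted p = 0.124 with an estimated correlation), with Icam1 at 4998 ± 1057 against 1825 ± 151 and the inhibitor subunit Nfkbie at 2508 ± 771 against 599 ± 330. Activation genes gave 8 higher and 2 lower of 20 (9 and 5 adjusted over the list alone; 0.00329, and adjusted p = 0.0647 with an estimated correlation), with the inhibitory receptor Pdcd1 at 7539 ± 1902 against 1776 ± 599 and the costimulatory receptor Tnfrsf9 at 3182 ± 1156 against 143 ± 89.8. Th2 genes gave 4 higher of 10 over all genes and over the list alone (0.00487, and adjusted p = 0.254 with an estimated correlation), including the IL-4 receptor Il4ra at 6868 ± 1754 against 2150 ± 985. Gata3, Il1rl1 and Ccr8 of the Th2 list are also VAT Treg genes. The activation list shares the same Treg core genes as in WT, Tnfrsf9 among them. Interferon-stimulated genes gave 3 lower of 28 over all genes and over the list alone (0.0444, and adjusted p = 0.38 with an estimated correlation), namely Irf7 (383 ± 101 and 764 ± 161), Ifit3 (11.6 ± 19.6 and 123 ± 70.6) and Oas3. The list was lost without any of Treg KO 2, Treg KO 3, Tconv KO 1, Tconv KO 3 or Tconv KO 4 (0.0636 to 0.234). It was also lost without Tconv WT 1, Tconv WT 3 and Tconv KO 3 together (0.0734) and under quantile scaling (0.0733). Irf7 was lost without Treg KO 1 (0.0919), Treg KO 4 (0.0712), Tconv KO 3 (0.0574) or the same 3 Tconv libraries (0.0544), Ifit3 without Treg KO 2 (0.0581) or 3 (0.0728) or by voom (0.0689), and Oas3 without Treg KO 1 (0.0612) or 3 (0.0705). Prostaglandin genes were not called (0.742), with 1 of 19 passing (2 higher and 2 lower adjusted over the list alone; the mean and camera differed in sign): the prostacyclin receptor Ptgir read 381 ± 236 in Treg KO against 58.0 ± 94.1 in Tconv KO (adjusted p = 0.0280), where Tconv KO 3 read 223. Its call was lost without any of Treg KO 1, 3 or 4 or Tconv KO 1, 2 or 4 (0.0635 to 0.0988), and by voom (0.109).

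Of the genes that passed, 238 were higher in Treg and 173 lower in both the WT and the KO comparison, where 13.1 and 7.54 would be shared by independent lists, and 0 passed in opposite directions. Of the 1163 genes called in either, 1110 had the same sign in both, with a correlation across genes of r = 0.85. Over all 14319 it was 0.53, with 9230 of the same sign. The comparisons share no libraries, but they come from 1 fit with a common estimate of each gene's spread. The 13.1 and 7.54 are therefore not a strict chance level. That 975 genes passed in KO and 599 in WT does not show a difference, since groups were larger in KO and the test of the difference called 0 genes.

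**Figure D3:**
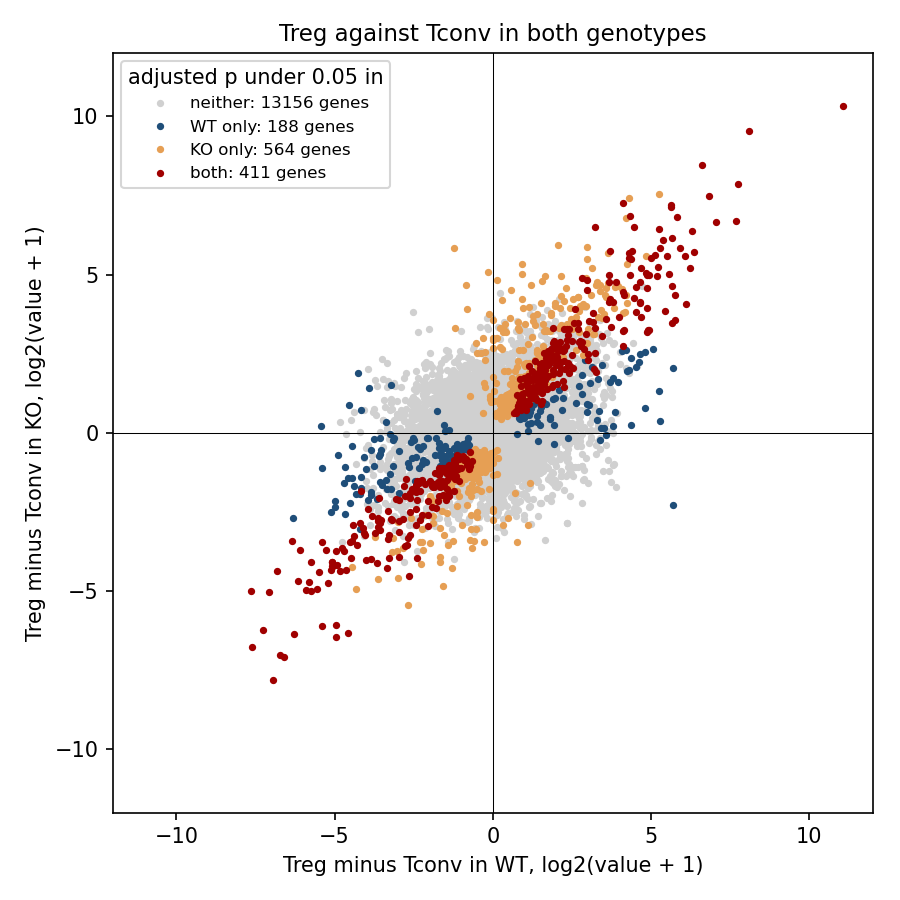
Each point is 1 of 14319 tested genes, with the log2 fold change of Treg against Tconv in WT on the x axis and in KO on the y axis, coloured by the comparison in which the gene passed in limma. The 411 genes that passed in both lie in the upper right and lower left, with 188 passing in WT only, 564 in KO only and 13156 in neither.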

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

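The tests on type 2 genes in Tconv and on Treg WT 2 were chosen only after the result was seen; those on Hpgd were written before it.

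Type 2 genes stood high in 3 of the 9 Tconv libraries, Tconv WT 1, Tconv WT 3 and Tconv KO 3, which come from both genotypes. Pparg, the nuclear receptor of fat Treg, read 316, 485 and 398 there and the eosinophil cytokine Il5 600, 426 and 940, where the other 6 Tconv libraries reached 52.4 for Il5. Treg cells as the source are argued against by Il5, whose lowest value in the 3 libraries, 426, lies above the 177 of the highest Treg library; with the Treg share set by Il1rl1, Cyp4f18 read 3.07, 1.00 and 4.42 where 256, 285 and 416 would be needed and Foxp3 20.6, 1.00 and 1.89 where 30.3, 33.6 and 48.6 would be, near the level needed in Tconv WT 1, and at least 10 of 4091 abundant Treg genes lay more than 2-fold short, but another Tconv library had 11, so that count leaves it open. Type 2 innate lymphoid cells were neither shown nor excluded: Arg1 read 16.5, 861 and 286, but also 16.8 in Tconv KO 1 and up to 47.6 in Treg, Calca read 506, 375 and 289, but 185 to 2864 in Treg, Il13 reached only 24.1, and the sort markers that would remove such cells are not given. The design names no group that these 3 libraries form, so no biological explanation was tested.

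Hpgd lay at 4.31 (3 reads) in the library labelled Treg WT 3, against 73.1 and 56.0 in the other two WT libraries. Loss of low transcripts in a library made from little RNA remains possible, since 10.9% of the 709 other genes at 30 to 100 in both other Treg WT libraries lay at or under that value in it, and the same share was 6.08% and 11.5% in Treg WT 1 and Treg WT 2. A KO library under a WT label cannot be told apart from a WT one here: of the 20 genes with the smallest p in a fit without it, 8 lay nearer to the WT mean, while the 6 other Treg libraries gave 4 to 10 whatever their label. Every statement on Treg WT in this series therefore includes a library whose genotype Hpgd does not show. No biological explanation was tested.

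Treg WT 2 stood apart from the other Treg libraries, with Nkg7, a cytotoxic granule gene, at 2984, Ifng at 1726 and Il1rl1 at 1725. Tconv cells in this library would bring all their abundant transcripts. Over 183 genes lower in Treg, the median implied Tconv share was 56.6%, but the other Treg libraries gave 39.5% to 52.1%, so that test decides nothing. Over the 5 genes that those libraries nearly lack, the median share was 2.10% and the highest 3.75% (Ly6c2), against 35.3% from Nkg7 and 52.4% from Ifng, which argues against Tconv cells as the source of these. No biological explanation was tested.

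Of 356 sets of values within a group of 4 or 5 libraries, 43 had 1 library far from the others. The cutoff aims at about 5% by chance, but any read is flagged where the other libraries had none. The 43 can therefore not be set against that share. Tconv KO 3, the deepest library, had 11 of them, and Tconv WT 3 and Treg KO 2 had 6 each. In Tconv KO 3, Abcc4 read 398 (the others 108 to 135), Gata3 5155 (1794 to 2117), Il1rl1 2548 (72.8 to 190), Nfkb2 1391 (695 to 808), Nfkbia 26248 (5480 to 8567), Pou6f1 269 (426 to 489), Scd2 1 (85.4 to 204) and Tnfrsf9 16.1 (120 to 264). Its total was 56.7 M reads (5.90 to 9.26), and Fxyd6 at 2.39 and Hpgd at 6.20 were above the 1 of all other Tconv KO libraries. In Tconv WT 3, Cd8b1 read 7.04 (117 to 129), Ctsb 2029.9 (3104 to 3278), Ptger4 884 (1162 to 1197) and Zbtb46 181 (83.2 to 89.9), while Fxyd6 read 2.01 and Rimkla 4.02 where the others had no reads. In Treg KO 2, Ccr7 read 745 (390 to 417), H2-Eb1 473 (1733 to 2021), Icam1 3430.2 (5346 to 5732) and Ms4a1 47.1 (16.6 to 18.5), and Cxcr5 read 24.0 and Rimkla 27.1 where the others had no reads. Reads in 1 library alone were also seen for Cd79b (14.4), Cyp4f18 (3.07) and Jcad (17.5) in Tconv WT 1, and for Ebi3 (5.06), Ky (7.09), Nicn1 (3.03), Slco2b1 (11.1) and Wipf3 (9.12) in Tconv WT 2. The same held for Dapl1 (1.97), Samd3 (7.81) and Slc26a11 (11.7) in Treg KO 4 and for Nphp4 (2.60) in Tconv KO 4, while Jcad read 1.89 in Tconv KO 5 (1 to 1.13). Capg read 1174 (2118 to 2276) and Klrk1 1124.5 (368 to 381) in Tconv WT 4. Treg KO 1 had Cd8b1 at 4.62 (90.1 to 126), Treg KO 3 had Il1rl1 at 12704 (10742 to 10916) and Zadh2 at 50.6 (122 to 129). Treg KO 4 had Lpl at 91.5 (138 to 147), and Tconv KO 4 had Srebf2 at 835 (961 to 1015). The effects of the deletion in Treg and Tconv differed for ribosomal protein genes (adjusted p = 0.00258) and for red cell and platelet genes (0.000695), both lost with an estimated correlation (adjusted p = 0.638).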

How the results depend on the processing

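The counts by voom and without 3 Tconv libraries, the pseudocount of 0, the thinning of Tconv KO 3 and the splits of the libraries were chosen only after the result was seen. The count of Treg genes changed by the deletion, 3, became 1 with a filter at 50, 1 with sample quality weights, 0 with only the groups compared in the fit and 0 by voom, and ran from 0 to 17 when single libraries were left out (0 without the library labelled Treg WT 3, 17 without Treg WT 1). The count for the difference of the effects ran from 0 to 2 (2 without Treg KO 2). In WT, the 599 genes between Treg and Tconv became 310 with only these groups in the fit and 288 by voom, and 339 to 664 without single libraries (339 without the library labelled Treg WT 3). Their 315 higher and 284 lower became 199 and 305 without Treg WT 1. They became 149 and 190 without the library labelled Treg WT 3, and 378 and 286 without Treg WT 2. The total of 975 in KO stayed within 1.5 times under every alternative run, and the 0 in Tconv stayed 0. The 380 genes lower in Treg KO became 241 without Treg KO 3 and 596 with quality weights, which is beyond 1.5 times. The cause was not tested, beyond the fewer libraries that leaving libraries out or fitting only the groups compared leaves. The libraries' numbers were not taken to pair them, since the labels do not say that they mark animals. Deviations of same-numbered Treg and Tconv libraries, which could share an animal, correlated at 0.024 to 0.079 in WT and 0.023 to 0.053 in KO. Same-numbered libraries of different genotype, which cannot share an animal, correlated at −0.022 to 0.074. This leaves unshown, rather than excluded, that the numbers mark animals. Since the series description gives fewer animals than libraries, some libraries share an animal whatever the numbers mean. The main p-values of Treg against Tconv and of the difference do not allow for that. With the replicate number as a block, 0 genes passed in Treg KO against WT. The Hpgd difference was then −3.01, with an unadjusted limma p under 0.05, as without the block, where the exact test gave 0.0571. With genotype and number together as the block, 507 genes passed between Treg and Tconv in WT and 841 in KO. Lists called were 1 in Treg KO against WT and 3 in Tconv by number, and 8 for the difference by genotype and number. Without a block they were 0, 1 and 2. As a hint from the data, a library correlated best with its own number in 3 of 3 (Treg WT against Tconv WT), 4 of 4 (Treg KO against Tconv KO), 3 of 3 (Treg WT against Treg KO) and 2 of 4 pairs (Tconv WT against Tconv KO), or 2, 3, 2 and 2 seen from the second group. Without single libraries the Hpgd difference ran from −4.34 to −2.44. With an estimated correlation, 0 lists were called in Tconv, 0 for the difference, 5 in WT and 6 in KO, and quantile scaling gave 1 in Treg KO against WT and 1 for the difference. Without Tconv WT 1, Tconv WT 3 and Tconv KO 3, 2 lists were called in Tconv and 0 for the difference. Without single libraries, 0 to 3 lists were called in Treg KO against WT (3 without the library labelled Treg WT 3 and 3 without Treg KO 2), 1 to 10 in Tconv (10 without Tconv KO 3, 7 without Tconv WT 2) and 1 to 12 for the difference (12 without Tconv KO 3). Foxp3, at 0.03 in Treg KO against WT, turned to −0.039 with quality weights, −0.33 with the block, and ran from −0.17 (without Treg WT 2) to 0.37 (without the library labelled Treg WT 3), none past the threshold. Of values for named genes that passed, 26 of the alternatives' values in Treg KO against WT, 64 in WT and 17 in KO no longer passed, and 31, 896 and 1087 kept their side. In KO, quality weights brought Ptger4 (adjusted p = 0.0409) and Zadh2 (0.0394) past the threshold, and voom Ptger4 (0.0495). No scaling moved the median of all genes by over 0.1. Count models of edgeR and DESeq2 were listed as alternatives but not run. The recovery test set for such models does not allow for the added 1 of the deposited values, although whole reads were recovered once it was removed. Depth limits low genes most: a value under 7.09 in Tconv WT 2 or 1.38 in Tconv KO 3 stands for 3 reads or fewer. Hpgd had no reads in 8 of 9 Tconv libraries. Its level in Tconv KO 3, 6.20 from 41 reads, lies above the value of 3 reads in the other Tconv KO libraries (3.34 to 4.65). Were reads independent molecules, depth alone would thus not account for the lack of reads in those. Without molecular identifiers reads are not independent, so this stays open.

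Splits of the libraries into groups of the same sizes bear on chance. For Treg KO against WT, 3 of 35 splits gave as many genes as the real 3 (highest other 4), so chance cannot be excluded. For Tconv (real 0, highest other 7) and for the difference (real 0, highest other 2), no gene passed, so splits cannot test the count. For Treg against Tconv, no other split reached the real count. In WT, 1 split of 35, the real one, gave 599 (highest other 106), and in KO 1 of 100 drawn gave 975 (highest other 516). These are the smallest shares that so few splits allow, which argues against chance without excluding it.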

Other observations

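Genes named for the groups of function, other than Pde7a, were chosen after their values were seen. Genes of the cAMP response gave 4 higher and 2 lower of 20 in WT Treg against Tconv and 8 and 4 in KO (adjusted over the list alone 6 and 4, and 10 and 6; camera adjusted p = 0.609 and 0.0993). The phosphodiesterase Pde7a, which breaks down cAMP, read 64.8 ± 48.3 in Treg against 1289 ± 446 in Tconv of WT (−4.70, adjusted p = 1.13e-05) and 111 ± 17.4 against 1513 ± 365 in KO (−3.74, 1.92e-05). In KO, the cAMP-induced repressor Crem read 9184 ± 2489 against 2945 ± 879 (adjusted p = 0.000270) and the growth factor Areg 3712 ± 1332 against 244 ± 363 (0.000466), of which Tconv KO 3 read 892 and the other Tconv KO libraries at most 129. Immediate early genes gave 1 higher and 3 lower of 29 in WT and 8 and 5 in KO (adjusted over the list alone 6 and 5, and 11 and 6; 0.929 and 0.150), with the phosphatase Dusp1 higher in Treg in both (adjusted p = 0.00542 and 7.85e-05); the list's mean and test differed in sign in WT. Glycolysis genes gave 2 higher of 18 in WT and 3 higher and 1 lower in KO (adjusted over the list alone 3 and 2, and 5 and 2; 0.984 and 0.150, with mean and test of opposite sign in WT), including the glucose transporter Slc2a3 at 1279 ± 268 against 524 ± 40.4 in KO (adjusted p = 0.000707). Oxidative phosphorylation genes gave 1 lower of 41 in WT and 1 higher and 1 lower in KO (the same over the list alone; 0.573 and 0.226), and Th17 genes 1 lower of 8 in each (0 and 1, and 1 and 1, adjusted over the list alone; 0.739 and 0.937), Il21 in both. Proliferation genes gave 0 of 29 in WT (0.134) and 1 lower in KO, the replication helicase subunit Mcm4 (1 adjusted over the list alone; 0.0439, and adjusted p = 0.173 with an estimated correlation), a list call lost without Treg KO 3 (0.0940), Treg KO 4 (0.0665), Tconv KO 1 (0.0780), Tconv KO 2 (0.0706) or Tconv KO 4 (0.0791). Ribosomal protein genes gave 1 lower of 40 in WT, Rpl10 (1 adjusted over the list alone; 0.000965, and adjusted p = 0.609 with an estimated correlation), lost without Tconv WT 3 (0.0625) or without Tconv WT 1, Tconv WT 3 and Tconv KO 3 together (0.0693), and 0 in KO (0.911). The signs of the cAMP and glycolysis lists in WT, and of the immediate early, macrophage and B cell lists in KO, turned under quantile scaling, and that of the ribosomal list in KO under median centring. Il21 was lost in WT without Treg WT 1, the library labelled Treg WT 3, Tconv WT 1 or Tconv WT 2 (up to 0.119).

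Macrophage markers gave 1 higher and 1 lower of 12 in WT and 1 and 2 in KO (adjusted over the list alone 1 and 1, and 3 and 2; 0.459 and 0.937). The galectin Lgals3 read 4760 ± 2180 in Treg against 1251 ± 471 in Tconv of WT and 5056 ± 2461 against 950 ± 287 in KO, and the tetraspanin Cd9 83.4 ± 42.7 against 473 ± 71.1 and 89.0 ± 22.5 against 343 ± 106. The lysosomal protein Cd68, named after its values were seen, read 8.92 ± 9.39 against 80.1 ± 63.8 in KO and was lost without any of Treg KO 3, Treg KO 4, Tconv KO 2, Tconv KO 4 or Tconv KO 5 (up to 0.128). Lgals3 was lost in WT without Treg WT 1 or the library labelled Treg WT 3 (up to 0.0976). Of dendritic cell markers 1 of 8 passed in each, H2-Eb1 (2 adjusted over the list alone in each; 0.396 in WT, and 0.00644 in KO, with adjusted p = 0.116 with an estimated correlation), and Cd74, the invariant chain, read 711 ± 472 against 211 ± 134 and 1200 ± 585 against 322 ± 161. H2-Eb1 was lost in WT without any 1 of the 3 Treg WT libraries, the one labelled Treg WT 3 among them, Tconv WT 2 or Tconv WT 3 (up to 0.102). Markers of type 2 innate lymphoid cells gave 4 higher of 9 in WT and 5 in KO (5 and 5 adjusted over the list alone; 0.000261 and 4.23e-07, and adjusted p = 0.307 and 0.129 with an estimated correlation), and Gata3, Klrg1, Il1rl1 and Areg on it are also genes of fat Treg. Red cell and platelet genes gave 1 lower of 7 in WT Treg (4 adjusted over the list alone; 0.00655, and adjusted p = 0.307 with an estimated correlation), lost without Tconv WT 3 (0.0621) or without the same 3 Tconv libraries (0.728), and 0 in KO (0.436). Neutrophil and mast cell markers gave 0 of 6 (0.416 and 0.879), B cell markers 0 of 8 (0.859 and 0.911) and adipocyte markers 0 of 6 (0.505 and 0.549), with the lipase Lpl at 106 ± 78.0 in Treg WT and 81.2 ± 42.4 in Tconv WT. Stromal markers gave 0 of 8 in WT and 1 higher and 1 lower in KO (2 and 1 adjusted over the list alone; 0.739 and 0.407), the mesothelial gene Lrrn4 at 271 ± 37.0 in Treg against 46.4 ± 50.6 and the endothelial gene Pecam1 at 256 ± 115 against 669 ± 279, the latter lost without Treg KO 3, Treg KO 4 or Tconv KO 3 (up to 0.0856). By fry, which asks whether a list moves one way without comparing it with other genes, 7 lists were called in WT, 12 in KO and 0 in the other comparisons.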
